A study of Homo sapiens with 4 samples.

How the data were processed

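RNA immunoprecipitation sequencing (RIP-seq) was carried out in U2OS, a human osteosarcoma cell line, carrying a lentiviral construct for Flag-tagged QKI7. QKI7 is an isoform of the RNA-binding protein QKI. There were 4 libraries: 2 of input RNA and 2 of RNA recovered with a Flag antibody (Flag-RIP). Per the labels' protocols, cells were cross-linked with ultraviolet light, lysed and sonicated before the precipitation, and libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq instrument. The labels describe the RNA as rRNA-depleted. They number the replicates 1 and 2 in each group but do not say whether the numbers stand for separate cultures, so p-values measure only the spread between these samples, which may be technical. A mock precipitation and cells without the tagged protein were not analysed here.

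The authors deposited 1 table of TPM values, a length-normalised share of each library, with 1 column per library. Per the submitters' processing notes, STAR and RSEM version 1.2.31 were used with the GRCh38 build. The annotation, filters and strand setting are not given in the sources used here. Each column sums to 1000000 within rounding over 26830 genes and 92 ERCC spike-in rows. ERCC spike-ins are synthetic RNAs, and when and in what amount they were added is not given in the sources used here. TPM values keep no depth, so the number of reads behind a value is unknown and no counting interval is given. TPM is a share of each library, so a few very abundant RNAs set the scale of all others, and TPM of RNAs shorter than a sequenced fragment depends on the length correction that RSEM applies. Where RSEM divides reads among near-identical genes, the values of the copies are uncertain. Among the tested genes, 63 had values identical to those of another gene.

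Spike-in rows were left out of the tests and kept in the TPM total. Genes with a mean TPM of at least 1 over the 4 libraries were tested (10415 genes). Flag-RIP was compared with input with limma version 3.58.1 in R version 4.3.3 (lmFit, and eBayes with a mean-variance trend) on log2(TPM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of low genes. The residual degrees of freedom were 2. In this fit the prior degrees of freedom were infinite, so every gene took its spread from the trend. The library medians of the RIP and input libraries lay 1.32 log2 units apart. Changes were therefore also computed after each library had been shifted to a common median. They are called centred changes below, and their fit had a prior of 5.72 degrees of freedom. This scaling was chosen beforehand as an alternative, but the choice to describe genes and lists on it was made after the shift of the medians had been seen. All adjusted p-values of single genes are from these limma fits. Plain folds are ratios of mean TPM.

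The 20 gene lists were fixed before the data were examined, as were the test, the filter, the alternatives and the rule for named genes. Older symbols were matched through the RefSeq gene table of the same build, which held 23987 of the file's symbols directly and 1395 more as a synonym of 1 gene, leaving 1448 unmatched. Coordinates are those of that table, GRCh38.p14. Lists were tested against all other tested genes with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested (18 lists), with adjustment over lists. Camera was run on the deposited scale, and list medians are of centred changes. Camera compares t-statistics, so a shift shared by all genes does not cancel fully where the spread differs between genes. List calls that changed at a common median are given below. The named genes were QKI, the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean TPM of at least 5 and no overlap between groups, and 2 members of each list, those with the largest change past the threshold as deposited, or with the highest mean TPM where fewer passed. Because that change is as deposited, members named for lists that were low relative to the median are often their exceptions. Readthrough, XIST and Y-linked genes were left out. Genes named outside this rule are marked as chosen after their values were seen.

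The procedure was tested on simulated data drawn around the means of the same 10415 genes, with a spread smoothed over expression, in 20 runs with 200 changed genes each. The centred fit recovered 86.0% of 2-fold and 100% of 4-fold changes, with 4.70% of calls false. Simulated genes varied independently, with the same spread in both groups. In the data, replicate deviations had an SD of 0.14 log2 units in input and 0.25 in Flag-RIP, and far more genes were called. These rates may therefore not hold for the data. A list of 30 genes shifted by 0.5 log2 units had an unadjusted camera p under 0.05 in 15 of the 20 runs, and a random list of the same size in 2.

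The alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean TPM of at least 5, quantile normalization, a common median, rescaling after the 20 most abundant rows were left out, eBayes without trend and with robust fitting, the replicate number as a block, and each library left out in turn. For the lists, camera with an estimated correlation and fry were run. The correlation was estimated with 2 residual degrees of freedom, so a list that does not pass in that version is not shown to be unshifted. Scaling to the spike-ins, the alternatives of the centred fit, and fry and estimated-correlation camera at a common median were added after the data were examined. Figures were drawn with matplotlib version 3.10.9. The planned tests of the QKI binding motif and of transcript length and GC content need transcript sequences and were not run. The list of mitochondrial-genome mRNAs had 0 matching rows.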

Results

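RIP-seq was used to ask which transcripts are bound by QKI7 in U2OS osteosarcoma cells that stably express the Flag-tagged protein. RNA recovered with the Flag antibody (n = 2 libraries) was compared with input RNA (n = 2 libraries). Values are TPM, which hold no read depth. Input replicate 1 had 6117 genes at a TPM of at least 1 and input replicate 2 had 7803. Flag-RIP replicate 1 had 11970 and replicate 2 had 12098. Over the 10415 tested genes, log2 values correlated at r = 0.989 between the inputs and at r = 0.962 between the RIP libraries, and at 0.849 to 0.917 between an input and a RIP library. These correlations are across genes, which are not independent replicates.

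The abundant noncoding RNAs made up most of every library and differed between the groups. 7SL RNA, the RNA of the signal recognition particle, took 82.2% ± 3.50 of the TPM in input and 41.6% ± 2.51 in Flag-RIP (SD, n = 2). 7SK RNA, which holds the transcription factor P-TEFb in an inactive complex, took 1.94% ± 0.19 in input and 15.1% ± 6.94 in Flag-RIP. RPPH1 and RMRP, the RNAs of RNase P and RNase MRP, together fell from 2.84% ± 0.40 to 1.04% ± 0.01. Protein-coding genes took 5.61% ± 0.90 in input and 12.9% ± 0.76 in Flag-RIP, and the ERCC spike-ins 3.33% ± 0.79 and 22.3% ± 4.77. Centred on the library medians, RN7SL1 fell by 2.36 on the log2 scale (limma adjusted p = 8.7e-04) and RN7SK rose by 1.56 (limma adjusted p = 0.0078). RN7SL1, RN7SL2 and RN7SK were the most abundant rows and are named for that reason, outside the fixed rule, and reads of RN7SL1 and RN7SL2 may be divided between these near-identical copies.

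**Figure D1:**
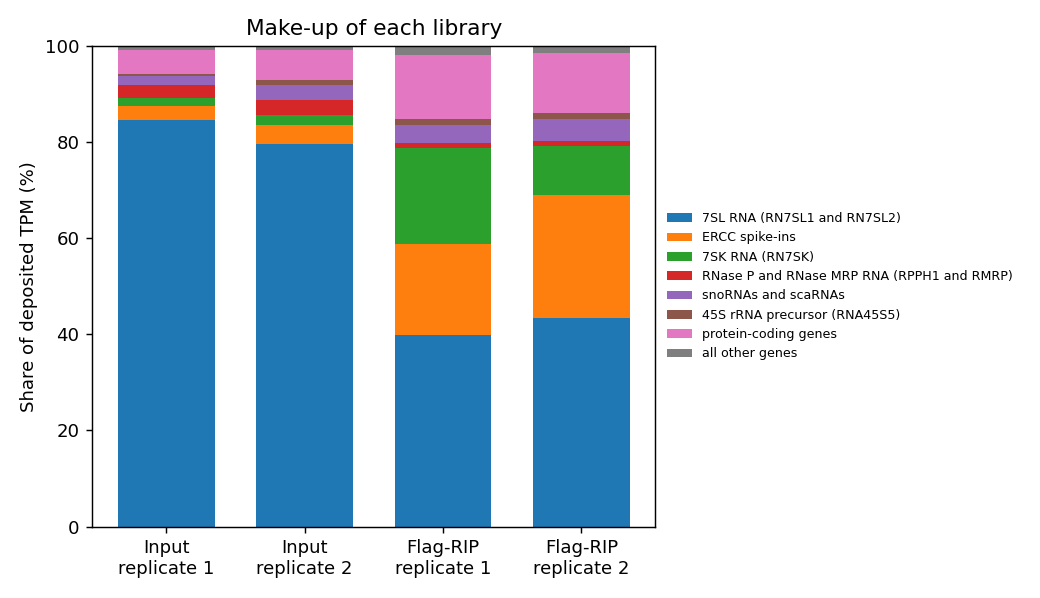
Share of deposited TPM (y axis, %) taken by 8 classes of RNA in each of the 4 libraries (x axis). 7SL RNA takes 79.7% to 84.6% of the input libraries and 39.8% to 43.4% of the Flag-RIP libraries, while the spike-in and 7SK shares are larger in the latter.

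In the deposited values, 9608 of the 10415 tested genes were higher in Flag-RIP and 33 were lower (limma, adjusted p under the 0.05 threshold), of which 7151 and 14 changed by at least 2-fold. The 2-fold counts depended on the pseudocount, with 8819 and 19 at 0.1 and 1767 and 9 at 5. The median change was 1.2 on the log2(TPM + 1) scale, against 1.68 with a pseudocount of 0.1, 0.60 with a pseudocount of 5 and 0.61 with no filter. The RIP values lay above both inputs for 10074 genes and below them for 88, a separation that chance gives for 33.3% of genes. With each library shifted to a common median, 1703 genes were higher and 2545 lower, 333 and 347 of them by at least 2-fold. These 2-fold counts were 753 and 778 with a pseudocount of 0.1, and 255 and 45 with a pseudocount of 5. Since log2(TPM + 1) understates the rise of low genes, centred lower calls, also within lists, can include genes that rose nearly like the median gene. FMR1, named after its value was seen, rose 3.19-fold in plain TPM against a median ratio of 3.32. It was called lower at -0.47. The direction of a typical gene depended on the scale, with 1842 higher and 2136 lower after quantile normalization, 3748 higher and 730 lower after the 20 most abundant rows were left out and the rest rescaled, and 319 higher and 6306 lower when libraries were scaled to the spike-ins. Changes below are centred on the library medians unless they are said to be as deposited. Centred counts fell to 332 higher and 322 lower without input replicate 1, and to 747 and 987 without input replicate 2. The deposited count of higher genes was 5396 without Flag-RIP replicate 1 and 6187 without replicate 2. In both same-numbered pairs of libraries, 4996 genes were at least 2-fold higher as deposited and 6 at least 2-fold lower, and after centring 267 and 136.

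A small set of transcripts stood far above the rest in Flag-RIP. MIAT, a long noncoding RNA known for repeats of the ACUAAC sequence that QKI binds, had a TPM of 0.76 ± 0.49 in input and 177 ± 44.4 in Flag-RIP (SD, n = 2), a centred log2 change of 5.35 (SE 0.18, limma adjusted p = 1.6e-05). FHL1, which encodes a LIM-domain protein, went from 7.39 ± 1.97 to 792 ± 351, a centred change of 5.19 (SE 0.28, limma adjusted p = 1.1e-04). The other protein-coding transcripts among the 8 largest increases were ERH at 4.24, FXYD6, a regulator of the sodium pump, at 3.90, and ATPIF1 (now ATP5IF1), the inhibitor of the mitochondrial ATP synthase, at 3.72. The RNAs SCARNA2 and SCARNA7, which guide modification of spliceosomal RNAs in Cajal bodies, rose by 4.36 and 3.88. LOC100507412, a noncoding RNA on an unplaced sequence, rose most, by 5.69. PEA15, at 3.41, is named after its value was seen. Adjusted p-values of these genes in the centred limma fit ranged up to 9.8e-04. All were higher in both RIP libraries than in both inputs, as the naming rule required of the 8 largest increases. In plain TPM the mean ratio was 232 for MIAT, 107 for FHL1 and 59.9 for ERH, against a median ratio of 3.32 over all tested genes. The RIP replicates differed in size for several of them, such as 560 and 222 TPM for ERH and 211 and 70.7 TPM for FXYD6. The ratio of MIAT rests on low and uneven inputs of 0.41 and 1.11 TPM. The change of LOC100507412 likewise rests on inputs of 0.32 and 1.03 TPM.

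In GRCh38, FHL1 lies on chromosome X from 136146702 to 136211359, and MIAT on chromosome 22 from 26646429 to 26676478. ERH lies on chromosome 14 from 69380128 to 69398299, FXYD6 on chromosome 11 from 117836981 to 117877430, and ATPIF1 on chromosome 1 from 28236124 to 28238100. SCARNA2 lies on chromosome 1 from 109100193 to 109100612 and SCARNA7 on chromosome 3 from 160514907 to 160515236. The table gives values per gene, so the part of each transcript that was recovered is not known.

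The 8 largest decreases as deposited were in rows named for microRNA precursors, the RNAs of RNase P and RNase MRP, and 3 protein-coding genes. MIR663A, a microRNA precursor gene on chromosome 20 from 26208186 to 26208278, had a TPM of 1630 ± 930 in input and 5.31 ± 0.44 in Flag-RIP. MIR3687-1 and MIR3687-2 had identical values, 793 and 149 TPM in the inputs, and are listed at 0 in both RIP libraries. Whether reads of these microRNA rows came from the precursors or from longer RNAs with the same sequence cannot be told here. RPPH1 fell by 1.44 as deposited (SE 0.10, limma adjusted p = 1.7e-43) and RMRP by 1.47 (SE 0.13, limma adjusted p = 5.4e-27). The protein-coding genes were ATP5E (now ATP5F1E), a subunit of the ATP synthase, which fell by 1.88 as deposited and 3.20 centred, and the histone H4 genes HIST1H4K and HIST1H4C, which fell by 1.61 and 1.17 as deposited. Without Flag-RIP replicate 1 the deposited decrease of HIST1H4C was 1.05 and no longer passed (limma adjusted p = 0.074). With robust variance fitting the centred decreases of ATP5E, HIST1H4K and HIST2H2BF did not pass (limma adjusted p = 0.062, 0.054 and 0.087). The H4 genes are near-identical in their coding sequences, so the division of reads among them is uncertain.

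**Figure D2:**
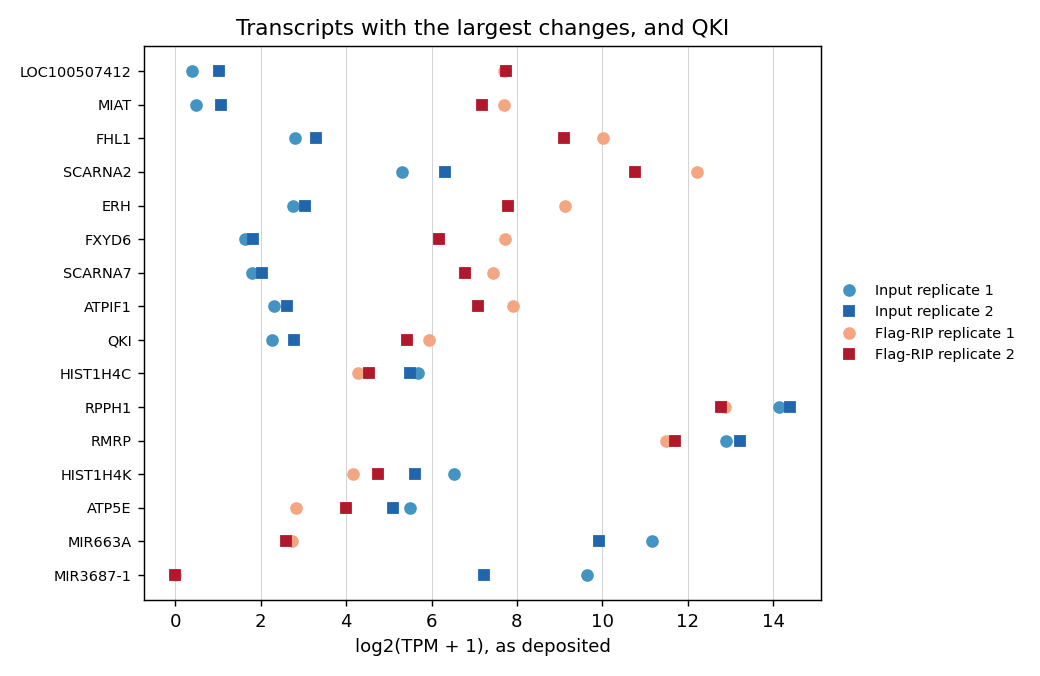
TPM of QKI and of the genes with the largest increases and decreases (MIR3687-2, identical to MIR3687-1, is not drawn), on a log2(TPM + 1) axis as deposited, with 1 point per library. The 4 libraries of each gene separate by group, as the naming rule required of all genes but QKI. The RIP values of MIAT, FHL1 and the SCARNA genes lie several log2 units above input.

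QKI itself was recovered with the tagged protein. Its TPM was 3.83 and 5.85 in the inputs and 60.7 and 42.0 in the RIP libraries. The log2 change was 3.16 as deposited (SE 0.33, limma adjusted p = 4.1e-20) and 1.85 centred (SE 0.18, limma adjusted p = 7.7e-04). When scaled to the spike-ins it was 0.65 and did not pass (limma adjusted p = 0.090). Reads of the transgene and of the endogenous gene cannot be told apart in a value per gene. Of 19 transcripts chosen from background knowledge as QKI targets, 8 were tested, of which 3 rose and 0 fell after centring, or 4 and 0 adjusted over the list alone. QKI, whose reads may include the transgene, is itself a member. Those that rose were SIRT2, a deacetylase, with a change of 2.18, QKI, and NUMB, an inhibitor of Notch signalling, at 0.50. CDKN1B, a cell cycle inhibitor, had 0.32, MAP1B 0.33, CTNNB1, the gene of beta-catenin, 0.18, HNRNPA1 0.04 and ADD3 -0.16, and none of these passed over all genes. The list lay above the other genes (median 0.32, camera adjusted p = 0.031; adjusted p = 0.93 with an estimated correlation), and the call was lost when any 1 of the 4 libraries was left out (camera adjusted p of 0.059 to 0.46), with no filter (0.106) and when scaled to the spike-ins (0.236).

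Transcripts for histones, ribosomal proteins, oxidative phosphorylation (OXPHOS) and the proteasome were low in Flag-RIP relative to the library medians. Of 47 replication-dependent histone genes, 41 fell and 2 rose (43 and 2 adjusted over the list alone), with a median of -1.60 (camera adjusted p = 1.3e-42; adjusted p = 0.43 with an estimated correlation). HIST2H2BF fell by 3.18 and HIST1H4J by 2.23, while HIST1H2BC rose by 1.22. Of 77 cytosolic ribosomal protein genes, 60 fell and 1 rose (63 and 1 adjusted over the list alone), with a median of -1.0 (camera adjusted p = 2.5e-25; adjusted p = 0.49 with an estimated correlation). RPL39 fell by 1.88 and RPS21 by 1.86, RPL31 had a change of -0.27 that did not pass, and RPL18 rose by 1.13. Of 71 nuclear genes for OXPHOS subunits, 61 fell and 0 rose (63 and 0 adjusted over the list alone), with a median of -0.92 (camera adjusted p = 1.5e-22; adjusted p = 0.43 with an estimated correlation). COX7B fell by 1.92 and NDUFS8 by 1.76, whereas NDUFB5 had 0.03 and did not pass. Of 32 proteasome genes, 22 fell and 2 rose (26 and 2 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 6.9e-06; adjusted p = 0.93 with an estimated correlation). PSMD8 fell by 1.67, PSMD12 rose by 0.63, and PSMB2 had 0.50 without passing. With no filter on low genes the proteasome call was lost (camera adjusted p = 0.211).

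The size of these medians depended on the pseudocount, filter and scaling, from -1.64 to -0.34 for ribosomal protein, -1.31 to -0.37 for OXPHOS, -2.22 to -0.85 for histone and -1.01 to -0.046 for proteasome genes. The values nearest 0 for OXPHOS, histone and proteasome genes are with no filter. There the library medians include many low genes, so the centring point differs. These decreases were relative to other genes. As deposited, 12 histone genes fell and 6 rose, 22 ribosomal protein genes rose and 0 fell, 21 OXPHOS genes rose and 1 fell, and 19 proteasome genes rose and 0 fell. HIST1H4J, RPL39, RPS21, COX7B, NDUFS8 and PSMD8 were named after their values were seen. The rise of RPL18 was lost without input replicate 1, input replicate 2 or Flag-RIP replicate 1 (centred 1.26, 0.99 and 0.68), that of HIST1H2BC without input replicate 2 (0.85), and that of PSMD12 without either input (0.69 and 0.56). The centred calls of RPL18 and HIST1H2BC were also lost with a pseudocount of 0.1 (0.73 and 0.83), rescaled without the 20 most abundant rows (0.69 and 0.79) and scaled to the spike-ins (0.49 and 0.59).

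Smaller shifts in the same direction were seen in metabolic and matrix genes. Of 20 glycolysis genes, 7 fell and 2 rose (11 and 3 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 0.031; adjusted p = 0.93 with an estimated correlation). GAPDH fell by 1.5 and ENO1 by 1.00, both named after their values were seen, while ENO2 rose by 0.85 and the glucose transporter SLC2A1 by 0.51. Of 26 extracellular matrix genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.037; adjusted p = 0.93 with an estimated correlation). SPARC, a collagen-binding matrix protein, rose by 1.83, LAMA5 had 0.32 without passing, and the protease inhibitor TIMP1, named after its value was seen, fell by 1.54. Both list calls were lost when any 1 library was left out (camera adjusted p of 0.080 to 0.40 for glycolysis and 0.11 to 0.80 for matrix) and with libraries at a common median (0.119 and 0.0526). The medians were above 0 with no filter, at 0.14 for glycolysis and 0.12 for matrix, and with a pseudocount of 5, at 0.068 and 0.096. With no filter the library medians include many low genes, so the centring point differs from that of the main values. The rise of ENO2 was lost without input replicate 1 (0.68) and that of SLC2A1 without either input (0.52 and 0.51), with a pseudocount of 0.1 (0.33), rescaled without the 20 most abundant rows (0.30) and scaled to the spike-ins (0.17).

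Nuclear-retained long noncoding RNAs had the highest median of the lists among genes past the filter. Of 11 members in the data 5 were tested, and all 5 rose (5 adjusted over the list alone), with a median of 2.64 (camera adjusted p = 3.9e-14; adjusted p = 0.43 with an estimated correlation). Beside MIAT, MALAT1 rose by 3.04 (7.14 to 152 TPM), and NEAT1, the scaffold of paraspeckles, by 2.64, TUG1 by 0.96 and PVT1 by 0.48, the last 3 named to complete the list. With no filter the list's median was 0.189 (camera adjusted p = 0.0448). It lay below those of the splicing factor (0.75), stress granule (0.74), Hippo (0.73), immediate-early and heat-shock (0.51) and RNA modification (0.44) lists. The mitosis (0.40), p53 (0.39) and zinc finger (0.192) lists also lay above it. MIAT, with 0.41 and 1.11 TPM in the inputs, passed the filter through its RIP values. Small structured noncoding RNAs went both ways, with 47 of 156 lower and 17 higher (47 and 18 adjusted over the list alone) and a median of -0.28 (camera adjusted p = 0.024; adjusted p = 0.93 with an estimated correlation). Without Flag-RIP replicate 1 this list call was lost (camera adjusted p = 0.22), as it was without replicate 2 (0.11), at a common median (0.26) and with a mean TPM of at least 5 (0.486). Of 20 snoRNA host genes, 3 rose and 8 fell (the same numbers adjusted over the list alone), with SNHG1 at 1.80 and SNHG3 at 1.41, and the list was not called (median -0.27, camera adjusted p = 0.52; adjusted p = 0.93 with an estimated correlation).

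**Figure D3:**
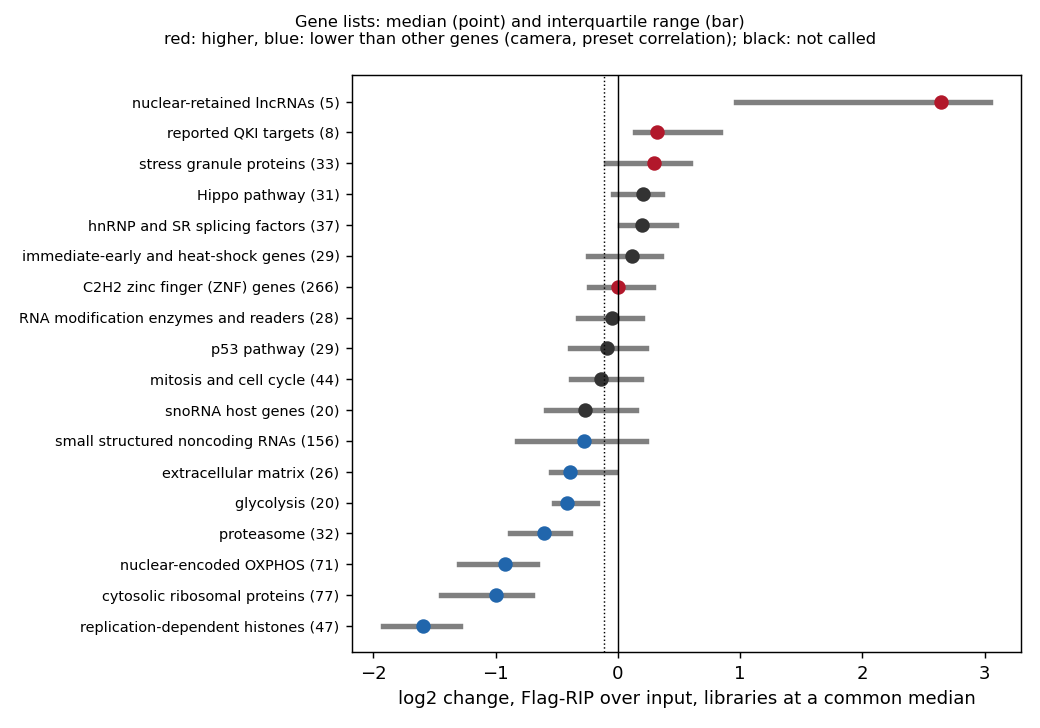
Centred log2 change of Flag-RIP over input (x axis) for the 18 tested gene lists, with the number of tested genes in brackets. Points are medians, colored by the camera call (red higher, blue lower, black not called), bars interquartile ranges, and the dotted line marks the median of all tested genes, -0.11. Histone, ribosomal protein and OXPHOS genes lie lowest and the nuclear-retained long noncoding RNAs highest.

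Transcripts that encode stress granule proteins were higher than other genes by a small margin. Of 33 tested, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.027; adjusted p = 0.93 with an estimated correlation). IGF2BP2, a reader of modified mRNA, rose by 2.51 (8.58 to 137 TPM) and PABPC1, the cytoplasmic poly(A)-binding protein, by 2.29 (53.4 to 692 TPM), while the core granule gene G3BP1, named after its value was seen, had -0.16 and did not pass. The list call was lost without Flag-RIP replicate 1 (camera adjusted p = 0.40), without Flag-RIP replicate 2 (0.21) and when scaled to the spike-ins (0.371). Its median ranged from 0.039 to 0.74 over the pseudocounts, filters and scalings. Of 266 C2H2 zinc finger genes, 52 rose and 23 fell (43 and 16 adjusted over the list alone), led by ZNF213 at 2.60 and ZNF460 at 1.48. Camera placed this list above other genes (adjusted p = 0.0020, and 0.93 with an estimated correlation). Its median was -0.00066 and its mean 0.04, against a median of -0.11 over all tested genes. The list's median ranged from -0.13 to 0.50 over the pseudocounts, filters and scalings. That call was lost without input replicate 2 (camera adjusted p = 0.11), without a variance trend (0.130) and with a mean TPM of at least 5 (0.169).

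The remaining lists were not called. Of 37 hnRNP and SR splicing factor genes, 11 rose and 0 fell (the same numbers adjusted over the list alone), with SRSF5 at 1.09 and SRSF11 at 0.76 (median 0.19, camera adjusted p = 0.155; 7.4e-04 with libraries at a common median, where the adjusted p was 0.665 with an estimated correlation). Of 31 Hippo pathway genes, 7 rose and 2 fell (the same numbers adjusted over the list alone), with the kinase TAOK1 at 0.82 and SAV1 at 0.64 (median 0.20, camera adjusted p = 0.40; 0.011 with libraries at a common median, where the adjusted p was 0.676 with an estimated correlation). Of 29 p53 pathway genes, 6 rose and 6 fell (the same numbers adjusted over the list alone), with SESN3 at 0.89 and MDM4, a p53 inhibitor, at 0.84. That list's median was -0.09 and its mean -0.02, above the median of -0.11 over all tested genes, and camera's direction was up (adjusted p = 0.67). Of 29 immediate-early and heat-shock genes, 7 rose and 5 fell (7 and 7 adjusted over the list alone), with ZFP36L1, an mRNA decay factor, at 1.94 and IER3 at 1.01 (camera adjusted p = 0.62). Of 44 mitosis and cell cycle genes, 6 rose and 12 fell (the same numbers adjusted over the list alone), with the spindle genes KIF23 at 0.62 and NUSAP1 at 0.58 (median -0.14, camera adjusted p = 0.17; median 0.40, adjusted p = 0.017 with no filter, where the centring point differs). Of 28 RNA modification genes, 3 rose and 3 fell (3 and 1 adjusted over the list alone), with RBM15, a subunit of the m6A writer complex, at 2.29 and WDR4, of the m7G methyltransferase, at 0.88. That list had a median of -0.05 and a mean of 0.03 (camera adjusted p = 0.62). With an estimated correlation, all 6 of these lists had an adjusted p of 0.93. Without input replicate 1, the rises of SRSF5, SRSF11, TAOK1, SAV1, SESN3, MDM4, IER3, KIF23, NUSAP1 and WDR4 were lost, at 0.81, 0.62, 0.81, 0.56, 1.02, 0.82, 0.91, 0.55, 0.54 and 0.80. Without input replicate 2, those of SESN3 (0.75) and NUSAP1 (0.62) were lost. The rise of SESN3 also did not pass with robust fitting or without a trend (limma adjusted p = 0.196 and 0.0514). That of NUSAP1 did not pass with a pseudocount of 0.1 (0.37), rescaled (0.34) or scaled to the spike-ins (0.19), nor did those of KIF23 (0.27) and IER3 (0.47) in the last.

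Of 28 markers of other cell types, 3 passed the filter, too few for a list test, and 2 rose after centring, both also adjusted over the list alone. These 2 were under 1 TPM in both inputs and passed the filter through their RIP values, so a marker this low in input could enter the test only if it was high in Flag-RIP. INS, the insulin gene, had 0.30 TPM in input and 5.23 in Flag-RIP, a centred change of 0.92, and CLDN5, an endothelial claudin, 0.205 and 4.02, a change of 0.71. RBFOX3, a neuronal splicing factor, had 0.16 and did not pass. The rise of INS was lost without either input (0.95 and 0.89), and that of CLDN5 without Flag-RIP replicate 2 (0.38), without either input (0.82 and 0.61) and with a pseudocount of 5 (0.12).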

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

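The tests in this part were chosen after the results were seen, except the comparison with abundance-matched lists. Signal outside the comparisons of the report was higher in Flag-RIP than in input for the 397 olfactory receptor genes, with a sum of 44.2 ± 18.6 TPM against 2.22 ± 1.44 TPM (SD, n = 2), and for the ERCC spike-ins, with a mean share of 22.3% against 3.33% of the TPM.

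Olfactory receptor genes were listed above 0 in 40 and 63 of 397 cases in the inputs, and in 86 and 279 in Flag-RIP replicates 1 and 2. The family's sum rose 6.0 times as much as the median gene's ratio of mean TPM, and mean TPM per gene in Flag-RIP replicate 2 differed 11.9-fold between the type 2 taste receptors (0.49) and the defensins (0.04). Most of these genes lie near the floor, with a median of 0.06 TPM for olfactory receptors and 0 for defensins in that library, so these values exclude neither a difference in depth nor an even background, as genomic DNA might give. The level was small, with a mean of 0.14 TPM per olfactory receptor gene in that library. An uneven background, unspliced RNA and low-level transcription were not tested.

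Most tested genes were higher in Flag-RIP as deposited (9608 of 10415), with a median log2 change of 1.2. After the 20 most abundant rows were left out and the rest rescaled, a median change of 0.45 remained. The genes were still those past the filter on deposited TPM, which genes higher in Flag-RIP pass more easily. This selection can itself raise the median, so whether those rows account for the whole shift is not decided. Scaled to ERCC the median change was -0.76, which restates the larger spike-in share in Flag-RIP. Because the amount and timing of the spike-ins are not given, a difference in the amount of endogenous RNA stays open. No biological explanation was tested, and how much of the shift reflects abundant RNAs, in the 20 rows or outside them, stays open.

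Histone, ribosomal protein, OXPHOS and proteasome genes had a pooled centred median of -0.99 (227 genes). Mean TPM over the 4 libraries is argued against as the cause, since 0 of 10000 random lists matched on it lay as low. The lowest of them had a median of -0.25. That mean includes the RIP values, and no lists were matched on input TPM, so abundance in input stays open. The 54 well-measured spike-ins had an interquartile range of 0.11 log2 units between RIP and input, but they are intact synthetic RNAs and when they were added is not stated, so a bias of library preparation or quantification on sonicated, short or non-polyadenylated mRNAs stays open. The recovery of short fragments from beads and lower binding to QKI7 are candidate explanations that stay open too. Without a mock precipitation in the data analysed here, these cannot be separated.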

How the results depend on the processing

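Scaling to the spike-ins and the alternatives of the centred fit were added after the data were examined. TPM values keep no depth, so how far depth limits any value is unknown, and with 1 library left in a group the lone library is assumed to vary like the other group. In none of the 15 settings of the single-gene test was a gene called on centred values in the direction opposite to its reported call. Of the centred values of the 50 named genes over all alternatives, 685 kept their side of the threshold, 46 lost the call and 9 gained one. A value that passed in neither fit counts among the 685 even where its sign changed. The values at a common median repeat the centred fit and are among the 685 by construction. The fixed tests of the QKI binding motif and of transcript length and GC content, and their alternatives, were not run. Unless stated otherwise, the cause of a change was not tested.

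As deposited, genes higher and lower in Flag-RIP numbered 9608 and 33, and on centred values 1703 and 2545. With no filter these were 15078 and 54, and 5590 and 10238, with 23463 genes tested. Of these centred calls, 1703 higher and 324 lower were also called with the filter, and 147 of the 10238 were at least 2-fold lower. Low genes change little on log2(TPM + 1), so they can lie below the median without being depleted. With a mean TPM of at least 5 the counts were 3476 higher as deposited, and 1025 and 1171 centred, with 3997 genes tested. As deposited they were 1842 and 2136 after quantile normalization, 1703 and 2545 at a common median, 3748 and 730 rescaled without the 20 most abundant rows, and 319 and 6306 scaled to the spike-ins, where 2678 were higher after centring. With single libraries left out, genes higher as deposited numbered 5396 to 9801, and centred genes 332 to 2294 higher and 322 to 3184 lower. Genes at least 2-fold higher in both numbered pairs were 7553 with a pseudocount of 0.1 and 2172 with a mean TPM of at least 5, against 4996. After centring, 595 were higher and 363 lower, 200 and 111, and 267 and 136 in these settings. Crossing the pairs gave 10 genes at least 2-fold lower, against 6.

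Scaled to the spike-ins, which moved the median change of all genes to -0.76, QKI had a change of 0.65 and these named genes changed sign from their deposited values: RPL18 (-0.29), RPL31 (-1.68), NDUFB5 (-0.47), HIST1H2BC (-0.19), TAOK1 (-0.052), SAV1 (-0.30), LAMA5 (-0.95), ENO2 (-0.31), SLC2A1 (-0.61), PSMB2 (-0.34), KIF23 (-0.51), NUSAP1 (-0.59), IER3 (-0.31), SRSF5 (-0.23), SRSF11 (-0.13) and WDR4 (-0.11). The deposited calls of MDM4 (0.36), ZNF460 (0.49), SPARC (0.43), PSMD12 (0.25) and ZFP36L1 (0.58) were lost on that scale. RPL31 also had -0.27 at a common median and -0.24 rescaled without the most abundant rows.

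List medians are of centred changes. With no filter, library medians were taken over 23463 genes, many under a mean TPM of 1, so the centring point moved. NDUFB5, for example, went from 0.03 to 0.58 with the same TPM values. Signs and sizes with no filter are thus on another reference than the rest, and camera compared the lists with these low genes too. With no filter, the calls of the QKI targets (0.14) and the proteasome (-0.046) were lost, matrix (0.12) and glycolysis (0.14) changed sign, mitosis genes (0.40) changed sign and gained a call, and Hippo (0.73), p53 (0.39), immediate-early and heat-shock (0.51), splicing factor (0.75) and RNA modification (0.44) genes gained a call. With a mean TPM of at least 5, small noncoding RNAs (-0.36), zinc finger genes (0.22), matrix (-0.42) and glycolysis (-0.51) lost theirs. Quantile normalization ended those of small noncoding RNAs (-0.13), matrix (-0.25) and glycolysis (-0.23), and splicing factors (0.22) gained one. At a common median, small noncoding RNAs (-0.28), matrix (-0.39) and glycolysis (-0.42) lost theirs while Hippo (0.20) and splicing factor (0.19) genes gained one. Rescaling without the most abundant rows ended the call of the QKI targets (0.16), and a pseudocount of 0.1 those of matrix (-0.64) and glycolysis (-0.73). Scaling to the spike-ins ended those of the QKI targets (0.048), small noncoding RNAs (-0.19) and stress granule genes (0.039), and mitosis genes (-0.45) gained one. Over the pseudocounts, filters and scalings together, medians of the lists called by camera ranged from -1.64 to -0.34 for ribosomal proteins, -1.31 to -0.37 for OXPHOS, -2.22 to -0.85 for histones, -1.01 to -0.046 for the proteasome, -0.75 to 0.12 for matrix, -0.89 to 0.14 for glycolysis, -0.39 to -0.13 for small noncoding RNAs, -0.13 to 0.50 for zinc finger genes, 0.039 to 0.74 for stress granule genes, 0.048 to 0.57 for the QKI targets and 0.19 to 2.80 for nuclear-retained long noncoding RNAs. Without a trend, zinc finger genes (-0.00066), matrix (-0.39) and glycolysis (-0.42) lost theirs and splicing factors (0.19) gained one.

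With single libraries left out, the medians of lists whose call changed were 0.26 to 0.38 for the QKI targets, -0.43 to -0.31 for matrix, -0.50 to -0.31 for glycolysis, 0.14 to 0.26 for splicing factors, -0.069 to 0.053 for zinc finger genes, -0.40 to -0.21 for small noncoding RNAs and 0.17 to 0.35 for stress granule genes. The calls of histone, ribosomal protein, OXPHOS and proteasome genes and of nuclear-retained long noncoding RNAs held with each library left out.

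Deviations of same-numbered libraries from their group means correlated at -0.07 (Pearson, across genes), and the labels do not say that a number marks a shared culture, so the numbers were not taken as pairs. With the replicate block, 9109 genes were higher and 27 lower as deposited, and 1720 and 2457 centred. The block ended the calls of the QKI targets (median 0.32, adjusted p = 0.10), stress granule genes (0.30, adjusted p = 0.0849), matrix (-0.39, adjusted p = 0.0649) and glycolysis (-0.42, adjusted p = 0.0597) by camera.

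None of the 11 list calls held with an estimated correlation, where camera's adjusted p was 0.431 for histones, OXPHOS and nuclear-retained long noncoding RNAs, 0.495 for ribosomal proteins and 0.929 for the others. At a common median it was 0.665, 0.676 or 0.689. With 2 residual degrees of freedom this version has little power, so these values do not decide whether a list moved. Fry, which does not compare a list with other genes, follows the shift of all genes as deposited. It gave an upward adjusted p of 0.0424 for ribosomal proteins, small noncoding RNAs and the proteasome, 0.0434 for OXPHOS and glycolysis and 0.0497 for matrix, opposite to camera, as were mitosis and snoRNA host genes (0.0424). For histones it was downward, as in camera, and did not pass (0.253). It gave 0.0424 for the Hippo, p53, immediate-early and heat-shock, splicing factor and RNA modification lists. At a common median no list called by camera passed in fry, with an adjusted p of 0.0824, except 0.105 for small noncoding RNAs and 0.589 for zinc finger genes.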

Other observations

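All tests in this part were chosen after the results were seen, and the members named were chosen after their values were seen. By RNA class, 90 of 203 tested transcribed pseudogenes rose after centring and 14 fell, with a median of 0.35. Among 310 long noncoding RNAs, 86 rose and 33 fell (median 0.12), and among 9474 protein-coding genes 1456 rose and 2405 fell (median -0.13). Of 9 POTE genes, 7 rose and 0 fell (median 1.80), and of 7 NPIP genes 6 rose and 0 fell (median 0.97). Both families were picked after their values were seen, and duplicated genes as a class were not tested. A gene under 1 TPM in both inputs passed the filter only through higher RIP values, which favours rises in classes low in input. Classes and families were not counted without the filter. Reads of these families, and of pseudogenes and their parents, are divided among near-identical copies, so single members are uncertain.

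The guide RNAs of the nucleus did not move as 1 group. Of 61 H/ACA snoRNAs, 4 rose and 27 fell (median -0.51), and of 63 C/D snoRNAs 6 rose and 10 fell (median -0.18). Of 16 Cajal body RNAs, 5 rose and 4 fell (median -0.12), with SCARNA2, SCARNA7, SCARNA9 and SCARNA28 at 4.36, 3.88, 3.62 and 3.49. RNU11, a spliceosomal RNA of the minor spliceosome, rose by 1.42.

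Across 9474 protein-coding genes, the centred change correlated with the genomic span of the gene at Spearman's rho = 0.27, and at 0.24 over the 9253 genes outside the 4 low lists. It correlated with mean TPM to a similar degree, at 0.25. Genes are not independent replicates, and genomic span is not transcript length. The tenth of genes with the shortest span (up to 5.11 kb) had a median of -0.45 and the tenth with the longest (from 152 kb) a median of -0.003.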
